A study of Arabidopsis thaliana with 9 samples.

How the data were processed

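Dry seeds of 3 Arabidopsis thaliana genotypes (Ler, dog1-1 and NILDOG1) were measured with 3 biological replicates each on 9 Affymetrix expression arrays, after biotin labelling with a one-cycle kit. The deposited values are log2 signals, 1 per probe set and array, normalized across the arrays by the authors with RMA per the submitters' processing notes; the RMA version and the chip definition are not given in the sources used here. The log base is not named there and was read from the values, whose arrays run from about 1.7 to 14.4. The tables hold no detection calls, no unnormalized intensities and no values of other kinds. The table holds 22810 probe sets, of which 64 Affymetrix controls were left out of the tests and 22746 were tested.

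Probe sets were given gene names from the deposited annotation table and matched by locus to a current gene table, which also supplied symbols and gene order. Of the probe sets tested, 13513 were listed with 1 gene, 503 with several and 8730 were not listed; 13436 had 1 locus in the gene table (59.1%, 13286 distinct loci, 144 of them with more than 1 probe set) and 77 had a gene that did not match. Coordinates are not printed, since the sources do not name the build of the array annotation. A gene with several probe sets was represented by the one with the highest mean over all arrays.

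The comparisons, gene lists, rule for named genes, window around DOG1 and most alternatives were fixed before the data were examined. Each pair of genotypes was compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a constant prior) in 1 fit of all 9 arrays, with genotype as the only term and 6 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all probe sets tested, with a threshold of 0.05 and no minimum change. The replicate numbers were not used to pair arrays, since the growth description mentions blocks but ties no number to a block. After removal of genotype means the correlations of arrays with the same number ran from -0.231 to 0.0299 (0 of 9 over 0.1). Those of other pairs ran from -0.151 to 0.275 (6 of 18 over 0.1). All pairs among Ler replicate 1, dog1-1 replicate 2 and NILDOG1 replicate 3 were over 0.1 (0.117, 0.172 and 0.125). Ler replicate 2 went with dog1-1 replicate 3 (0.135) and NILDOG1 replicate 1 (0.275), and Ler replicate 3 with dog1-1 replicate 1 (0.103). Blocks numbered differently in each genotype are therefore not excluded, and no such blocks were fitted.

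For a joint count of both lines, probe sets were taken where the mean of dog1-1 and NILDOG1 differed from Ler in the same fit and both changes had the same sign, without a test of each line on its own. The share of probe sets with Ler between both lines and the correlation of the changes were set beside 100 simulations each, and so, after the data were seen, was the share of NILDOG1 calls with the same sign in dog1-1. A group mean within the range of the TrpnX control probe sets (up to 2.56) was taken as background. The window from AT5G40000 to AT5G52000 was tested with a two-sided Fisher's exact test over nuclear probe sets with 1 locus (13367). Both chromosome 5 stretches in the figures were defined after the data were seen, by linking calls at most 100 named loci apart around windows of 40 named loci; a first definition, also made after seeing the data, merged the windows themselves, and was dropped.

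The 15 lists held 320 members, of which 82 had a named probe set. Camera with a preset correlation of 0.01 was run on the 9 lists with at least 3 measured members and adjusted over 27 tests, with an estimated correlation beside it. The lists were LEA proteins, heat shock proteins, seed storage proteins, oil body proteins, abscisic acid synthesis and breakdown, abscisic acid signalling, seed maturation and dormancy regulators, gibberellin genes, cell wall loosening, raffinose family sugars, antioxidant enzymes and oil mobilisation, and as markers of other tissues photosynthesis, seed coat and endosperm. Named genes were DOG1; in each comparison the 5 largest rises and 5 largest falls past the threshold without overlap of the arrays, from probe sets with 1 gene; for each list and comparison up to 2 members per direction past the threshold, or the one with the highest mean signal where none passed; 20 genes always to be named, of which only CP1 had a named probe set; and the 5 largest changes around DOG1. The rule gave 48 genes, none with a second probe set, and DOG1 had 0 named probe sets. The other genes named in the text (members that complete a count, the genes called in NILDOG1 away from the stretches, and members of families) and the probe sets without a gene were chosen after their values were seen.

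The pipeline was tested on simulated data: of 200 changed genes it recovered 43.1% at a log2 change of 0.5, 99.3% at 1 and 100% at 2, with 9.9 false calls on average. The list test called a shifted list in 20 of 20 simulations with 1 false list in total. The simulated noise was independent between genes, so this does not give the rate of false lists where members correlate. In the data the estimated correlation was 0.188 for the heat shock list and 0.178 for the cell wall list. Alternatives numbered 26 settings: a filter on dim probe sets (mean of at least 5 in at least 1 genotype), median centring, renewed quantile normalization, an intensity trend with a robust prior, fits of the compared groups alone, a replicate block, removal of probe sets that can match several genes, array weights, a minimum log2 change of 1, each array left out, a narrower window, averaged probe sets, an estimated correlation, fry, and removal of the loci around DOG1. Added after seeing the data were removal of Ler replicate 1 and dog1-1 replicate 3 together, centring on the 18 hybridization control probe sets, removal of both stretches, and the settings of the correlation across genes.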

Results

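Gene expression was measured in dry seeds of Arabidopsis thaliana, collected fresh at the end of maturation, on 9 Affymetrix arrays. The 3 genotypes had 3 biological replicates each, every one a bulk of plants. Ler (Landsberg erecta) was the wild type, with DOG1 (DELAY OF GERMINATION 1, a regulator of seed dormancy) labelled as low. In the dog1-1 mutant DOG1 was labelled as absent, and in NILDOG1, a near isogenic line that carries DOG1 from the Cvi accession, as strong. DOG1 (AT5G45830) had no probe set under its name in the annotation used here, so its own level was not analysed here and the labels could not be checked against it. All values are log2 signals, and errors are standard deviations over 3 replicates unless a standard error (SE) is named. The array medians lay between 3.51 and 3.60. Pearson correlations between arrays of 1 genotype lay between 0.992 and 0.996, and those between Ler and dog1-1 between 0.976 and 0.983. The first principal component held 58.6% of the variance and set the dog1-1 arrays (35.6 to 44.7) apart from the others (-23.1 to -16.7). Ler replicate 1 stood apart on the second component at 30.6, and the 25S ribosomal RNA control was low on that array (7.33) and on dog1-1 replicate 3 (8.04) against 9.86 to 11.9 elsewhere. The number of arrays limits the precision of every value below.

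The comparison of dog1-1 with Ler asks what changes in mature seeds that lack DOG1, though other differences between these genotypes, weighed at the end, are not separated from its loss. AT2G34740, a gene of the PP2C phosphatase family, fell from 10.18 ± 0.22 to 5.91 ± 0.33 (n = 3), 19.3-fold. AT1G27030 fell from 7.46 ± 0.017 to 3.71 ± 0.24, 13.4-fold. The small heat shock protein genes HSP17.6C (AT1G53540) and HSP17.6B (AT2G29500), which encode chaperones stored in dry seeds, fell 10.9-fold and 10.2-fold. In the other direction, AT4G38410 and AT1G54410, which encode dehydrins, rose 16.0-fold and 15.9-fold, from 3.38 ± 0.13 to 7.37 ± 0.52 and from 4.04 ± 0.25 to 8.03 ± 0.29. AT5G14450, a lipase-family gene, rose 15.9-fold, and CP1 (AT4G36880), a cysteine protease gene, rose 8.14-fold from 4.88 ± 0.19 to 7.91 ± 0.36. The largest named rise was that of AT5G43450, a dioxygenase-family gene close to DOG1 on chromosome 5, from 2.95 ± 0.17 to 8.11 ± 0.079, 35.9-fold (8.10 ± 0.17 in NILDOG1), and LUL1 (AT5G03200), a ubiquitin ligase gene near the start of that chromosome, rose 12.4-fold (6.65 ± 0.075 against 7.20 ± 0.19 in NILDOG1). AT5G38780, a methyltransferase-family gene, fell 8.46-fold, and NILDOG1 was lower there as well (6.04 ± 0.026 and 7.11 ± 0.052 against 9.12 ± 0.30 in Ler).

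**Figure D1:**
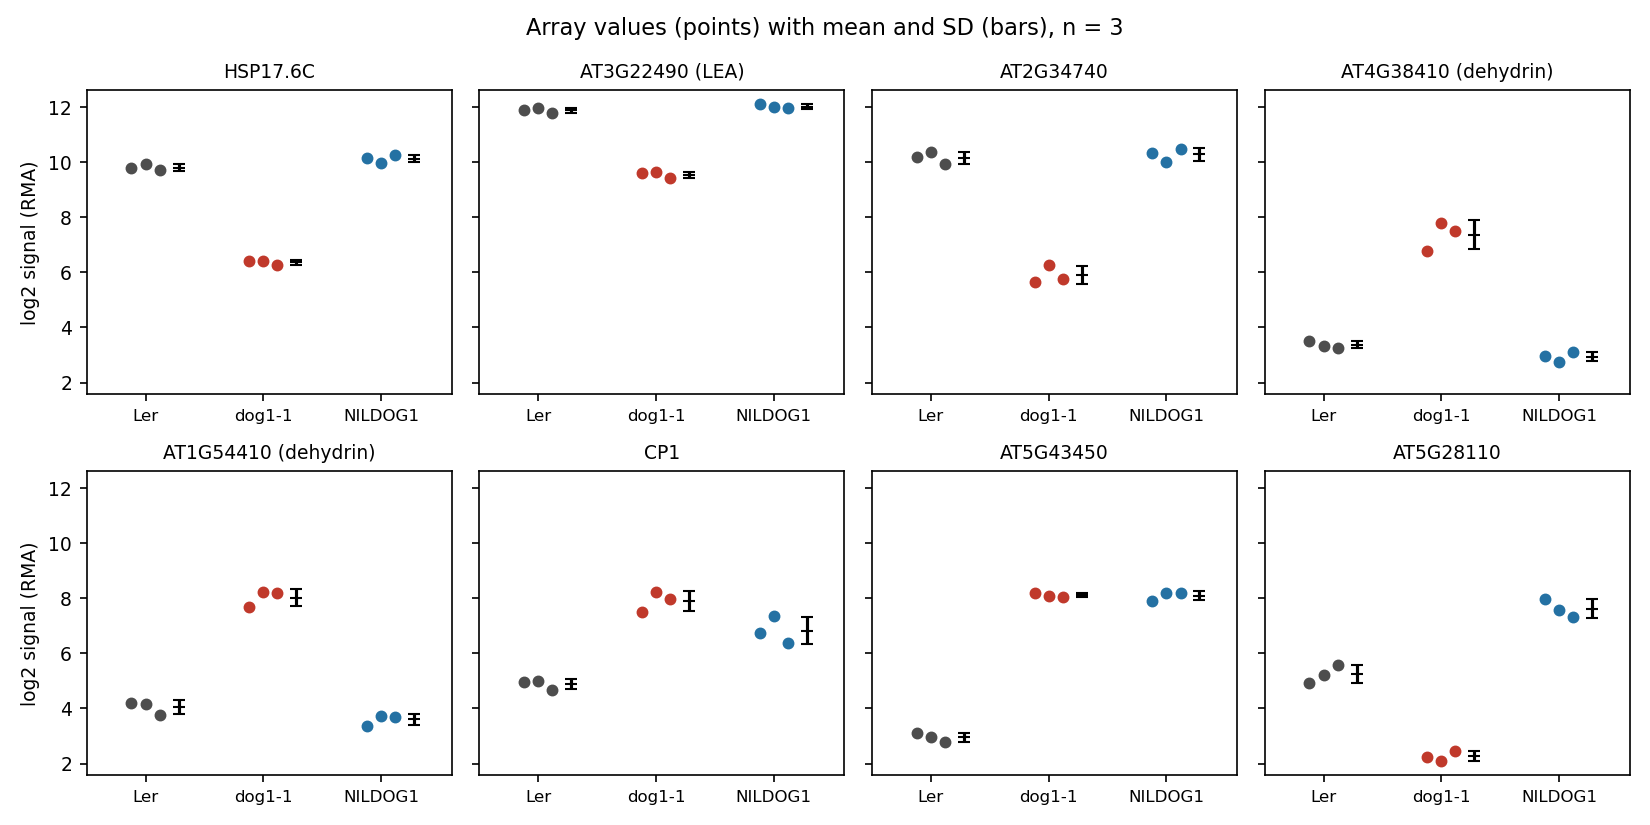
Log2 signal of 8 genes on each of the 9 arrays (points), with the mean and the SD over 3 replicates (bars) beside them. HSP17.6C, AT3G22490 and AT2G34740 lay lower in dog1-1 than in Ler and NILDOG1, both dehydrin genes lay higher, and AT5G43450 was raised alike in dog1-1 and NILDOG1 (8.11 and 8.10).

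With limma, 3095 of 22746 probe sets passed an adjusted p of 0.05 between dog1-1 and Ler (13.6%): 1894 were higher and 1201 lower in dog1-1, and 784 changed at least 2-fold (554 higher, 230 lower). Without adjustment 5816 had a p under 0.05. The 3 arrays of dog1-1 did not overlap those of Ler for 6128 probe sets (26.9%, where chance gives 10%). Of the probe sets called, 1531 had a single named gene. Among those without one, the largest rises were 5.93 and 4.93 and the largest falls -4.05 and -3.95 on the log2 scale. The hybridization control probe sets were lower on the dog1-1 arrays (8.81 to 9.14) than on the Ler arrays (9.19 to 9.57). When each array was centred on them, a choice made after the data were seen, the median change of all probe sets became 0.31, the count (genes changed, dog1-1 against Ler) became 5173 with 93.7% higher, and 325 of the 1201 falls still passed. The changes given here are relative to the centre set by the deposited normalization.

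The heat shock protein list, fixed with the other lists in advance, moved as a group. Of its 25 members 9 had a named probe set; 0 rose, 7 fell and 2 did not pass, with a mean change of -1.81 (camera, adjusted p = 1.65e-11, and adjusted p = 0.0463 with an estimated correlation). Adjusted over the list alone, 0 rose and 8 fell. HSP17.6C went from 9.81 ± 0.12 to 6.36 ± 0.088, HSP17.6B from 8.10 ± 0.14 to 4.74 ± 0.95, HSP22.0 (AT4G10250) from 5.86 ± 0.058 to 3.42 ± 0.72, and HSP18.5 (AT2G19310) from 9.98 ± 0.094 to 7.87 ± 0.36. All 7 that fell were also lower and past the threshold after centring on the hybridization controls.

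The LEA proteins, which protect cells as seeds dry, moved in both directions. Of 51 members 35 had a named probe set; 6 rose, 11 fell and 18 did not pass, and adjusted over the list alone 7 rose and 11 fell. The mean change was -0.035 and the list was not called (adjusted p = 0.216, and adjusted p = 0.511 with an estimated correlation). After centring on the hybridization controls its mean turned to 0.32, with 7 higher and 8 lower. AT3G22490 fell from 11.90 ± 0.087 to 9.55 ± 0.11, M17 (AT2G41260) from 11.58 ± 0.094 to 9.96 ± 0.28, AT3G53040 from 12.57 ± 0.18 to 10.97 ± 0.21 and AT4G39130, a dehydrin, from 8.57 ± 0.27 to 6.64 ± 0.34. The rises were led by the dehydrins AT4G38410 and AT1G54410, followed by COR47 (AT1G20440), which rose from 3.29 ± 0.10 to 5.62 ± 0.32. AT3G15670, whose probe set had the highest mean signal of the list, had 13.90 ± 0.0052 in Ler and 13.85 ± 0.046 in dog1-1, close to the highest signals on the arrays. The 18 genes that did not pass had mean levels over all arrays from 2.07 to 13.89. AT2G33690 among them was at background in Ler (2.12) and dog1-1 (2.04). Near either end of the scale, not passing does not show that a level was unchanged.

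**Figure D2:**
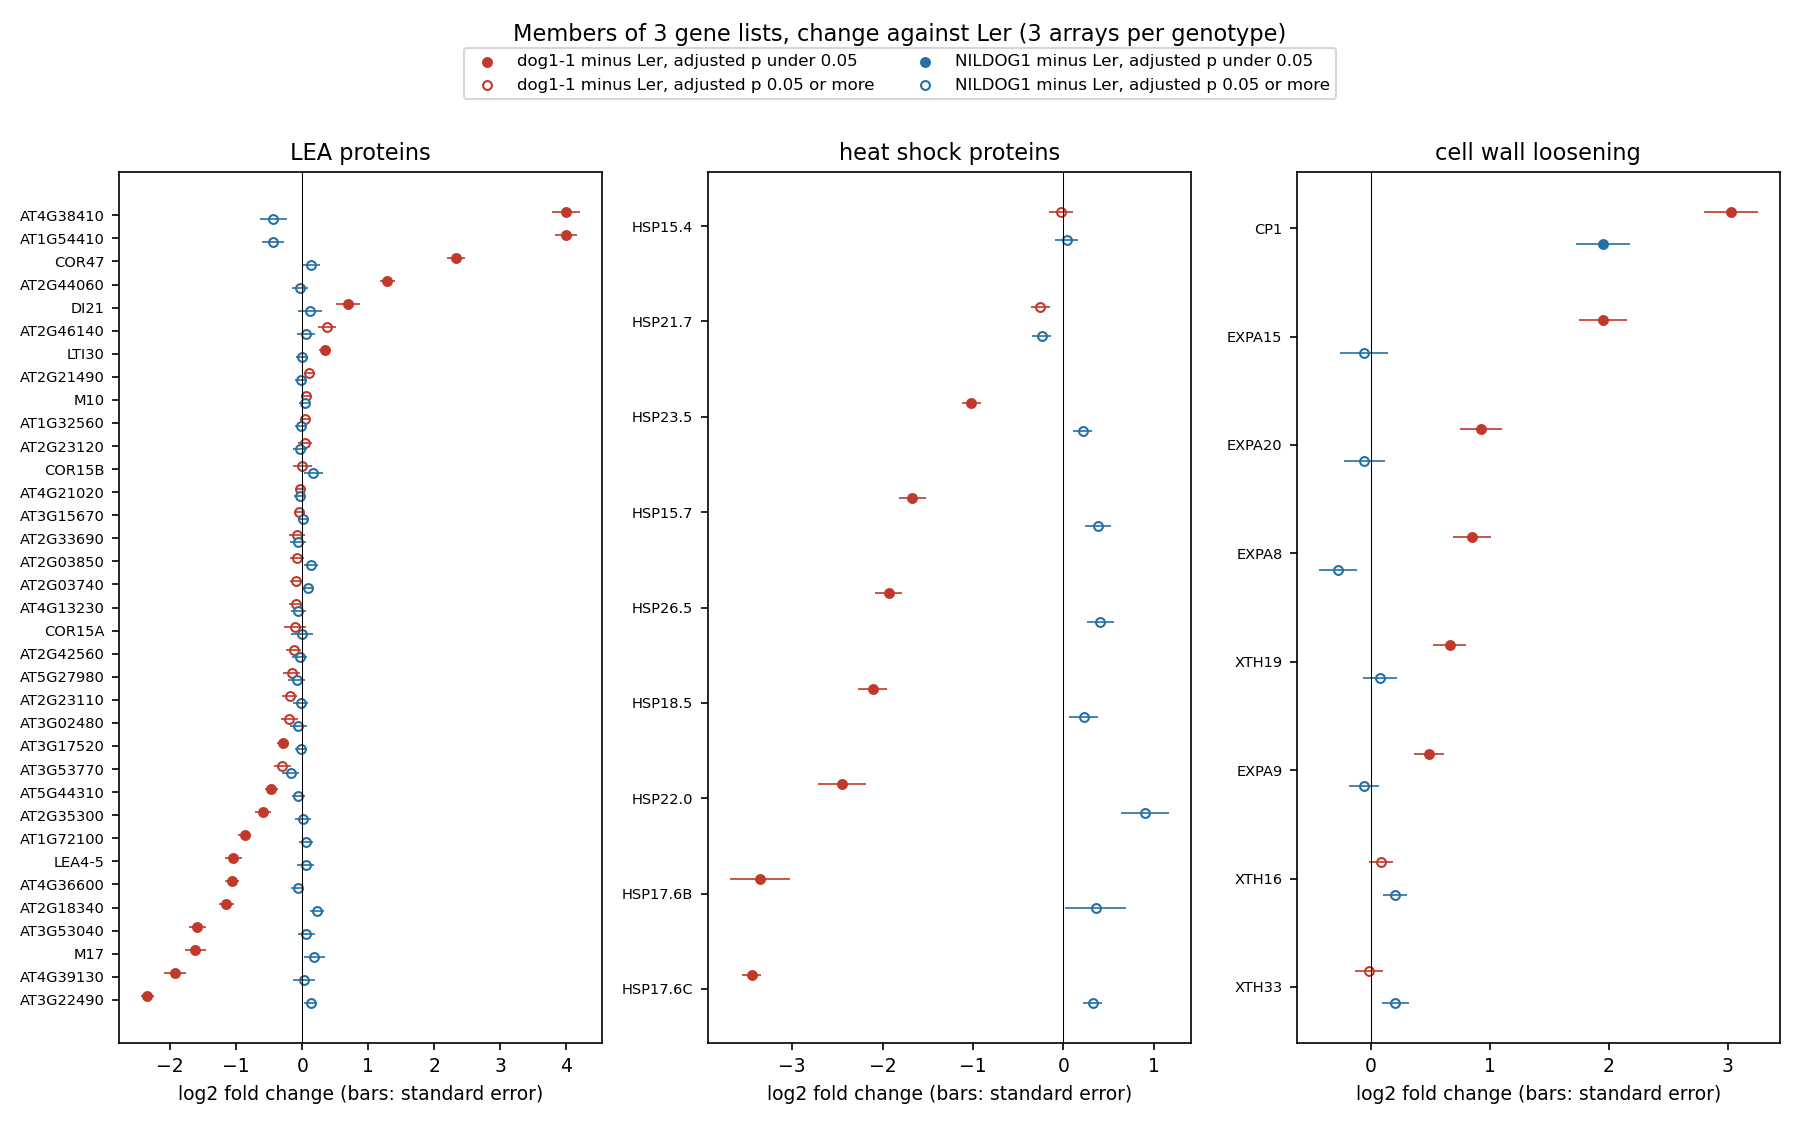
Log2 fold change against Ler of each named member of the LEA, heat shock protein and cell wall loosening lists in dog1-1 (red) and NILDOG1 (blue), with the standard error as bars and filled points for an adjusted p under 0.05. In dog1-1, 7 of 9 heat shock genes fell, 6 of 8 genes of the cell wall list rose and 17 of 35 LEA genes passed in both directions; in NILDOG1 only CP1 passed among the genes drawn.

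Of the cell wall loosening list, 8 of 20 members had a named probe set; 6 rose, 0 fell and 2 did not pass, with the same counts adjusted over the list alone and a mean change of 1.00 (adjusted p = 8.59e-07, but adjusted p = 0.0925 with an estimated correlation). EXPA15, EXPA20, EXPA8 and EXPA9, expansin genes, rose by 1.95, 0.93, 0.85 and 0.49, the last from a signal of 2.59 close to background. XTH19, a xyloglucan-modifying enzyme gene, was at background in Ler (2.45 ± 0.044, where the TrpnX control probe sets, whose transcript seeds lack, had 1.82 to 2.56) and reached 3.11 ± 0.33 in dog1-1. The largest rise of that list, 3.03, was that of CP1, a protease gene rather than a wall-modifying one. XTH16, which did not pass, was at background in Ler (2.40) and dog1-1 (2.48). Among the 5 measured seed storage protein genes 1 rose (AT1G03890, a cruciferin-like gene, by 0.69), 2 fell (AT2G18540 by 0.97 and AT4G36700 by 0.95, both of the cupin family) and 2 did not pass (adjusted p = 0.967); the mean of -0.19, the median of 0.084 and the upward test differed in sign, and after centring on the hybridization controls the mean was 0.17. PAP85, with the highest mean signal of them, had 13.45 ± 0.066 in Ler and 13.54 ± 0.030 in dog1-1. Of 4 oil body protein genes 0 rose with limma, 1 fell (AT3G18570, an oleosin-family gene, -0.43, adjusted p = 0.0255) and 3 did not pass (adjusted p = 0.586 for the list); without adjustment 2 were lower. After centring on the hybridization controls the fall of AT3G18570 no longer passed, and 1 of the 4 was higher and 0 lower. All 3 measured regulators of maturation and dormancy passed: SPT, a bHLH factor that controls germination, rose by 0.88, while BZIP53, an activator of maturation genes, fell by 0.64 and DOGL4 (AT4G18650), a gene related to DOG1, fell by 0.35. The list as a whole was not called (adjusted p = 0.626), and after centring on the hybridization controls neither fall passed and that of DOGL4 turned to 0.0058.

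Hormone genes were thinly covered. EEL, a bZIP factor of the abscisic acid pathway and the single measured member of its list of 30, rose from 7.61 ± 0.098 to 8.46 ± 0.16, 1.81-fold. Of 4 gibberellin genes (the receptors GID1A, GID1B and GID1C, and SLY1) 0 rose, 0 fell and 4 did not pass with limma, while 2 were lower at an unadjusted p under 0.05 (camera, adjusted p = 0.217 for the list). GID1A had a change of -0.28 (adjusted p = 0.111). GID1B was at background in Ler (2.54), dog1-1 (2.44) and NILDOG1 (2.50), so its change cannot be judged. ICL, an enzyme of oil mobilisation, rose by 0.43, and the 2 other measured genes of its list, AIM1 and SDP1, did not pass (adjusted p = 0.251 for the list). Of 6 photosynthesis genes, taken as markers of green tissue, 2 rose, 1 fell and 3 did not pass (adjusted p = 0.0889): RCA, the activase of Rubisco, rose from 4.30 ± 0.17 to 5.82 ± 0.14, LHCB4.2 rose by 0.50 (adjusted p = 0.0409) and LHCB4.1 fell by 0.62. Adjusted over the list alone 4 rose and 1 fell, and after centring on the hybridization controls 4 were higher, 0 were lower and the fall of LHCB4.1 no longer passed. LHCB4.1 (AT5G01530), like EXPA9 (AT5G02260) above, lies at the start of chromosome 5, where NILDOG1 also differed from Ler at 15 loci. Both seed coat genes (DFR and BAN, 2.84 ± 0.10 in Ler and 2.83 ± 0.21 in dog1-1 for BAN) did not pass, 1 of them lower without adjustment. Of the 2 endosperm genes IKU2 fell by 0.42, which no longer passed after that centring. AGL62, at background in Ler (2.35) and dog1-1 (2.21), did not pass. Lists of fewer than 3 measured genes were not tested. No member of the lists for abscisic acid synthesis, raffinose family sugars or antioxidant enzymes had a named probe set, so these were not analysed here.

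NILDOG1 against Ler compares seeds with a stronger DOG1 allele, and any other Cvi sequence that came with it, to the wild type. Its changes cannot be assigned to DOG1 alone. AT5G43450 rose from 2.95 ± 0.17 to 8.10 ± 0.17 (n = 3), 35.5-fold, and LUL1 from 3.02 ± 0.29 to 7.20 ± 0.19, 18.1-fold, as both did in dog1-1. AT5G45540 rose from background in Ler (2.3 ± 0.32) to 5.95 ± 0.47, so no fold is given, and AT5G48110, a terpene synthase family gene, rose 4.57-fold from 3.38 ± 0.31 to 5.57 ± 0.57. AT5G28110 rose 5.21-fold, from 5.25 ± 0.32 to 7.63 ± 0.35, and was at background in dog1-1 (2.27 ± 0.19); its probe set has the suffix of those that can match several genes. The largest falls were those of AT5G48350 (-2.11, SE 0.15), AT5G38780 (-2.01, SE 0.13), AT5G46040 (-1.52, SE 0.14), AT5G43822 (-1.47, SE 0.17) and AT4G18975 (-1.46, SE 0.12), and all of these also fell in dog1-1 (-2.14, -3.08, -1.51, -1.54 and -1.67). AT5G46040 was at background in both lines (2.52 and 2.51), so its changes are lower bounds in size.

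Between NILDOG1 and Ler 124 probe sets passed (73 higher, 51 lower, 71 at least 2-fold), against 1343 with an unadjusted p under 0.05, and 69 of them had a named gene. For 9.32% of all probe sets the arrays did not overlap, where chance gives 10%. The count (genes changed, NILDOG1 against Ler) fell to 80, 65 and 67 without Ler replicate 3, NILDOG1 replicate 1 and NILDOG1 replicate 2. No named LEA gene passed with limma (0 of 35, with 1 lower at an unadjusted p under 0.05; adjusted p = 0.951 for the list), and AT3G15670 had 13.91 ± 0.011. The heat shock list was slightly higher in NILDOG1, with a mean of 0.29 (camera, adjusted p = 6.38e-04, but adjusted p = 0.201 with an estimated correlation); 0 rose, 0 fell and 9 did not pass, 4 were higher and 1 lower without adjustment, and adjusted over the list alone 2 rose. HSP18.5 had 9.98 ± 0.094 in Ler and 10.20 ± 0.17 in NILDOG1. In the cell wall list 1 rose, 0 fell and 7 did not pass, also adjusted over the list alone (adjusted p = 0.127 for the list): CP1 rose 3.87-fold to 6.83 ± 0.48. In every other list with a measured member 0 rose and 0 fell, also adjusted over the list alone, and without adjustment 1 endosperm gene was lower. The adjusted p of the list test was 0.672 for seed storage, 0.191 for oil body, 0.967 for regulators, 0.453 for gibberellin, 0.586 for oil mobilisation and 0.423 for photosynthesis. GID1A was 9.05 ± 0.013 in Ler and 9.09 ± 0.11 in NILDOG1, EEL 7.61 ± 0.098 and 7.57 ± 0.14, DOGL4 9.43 ± 4.58e-04 and 9.62 ± 0.10, ICL 12.94 ± 0.22 and 12.99 ± 0.13, LHCB4.1 8.75 ± 0.43 and 8.96 ± 0.17, PAP85 13.45 ± 0.066 and 13.50 ± 0.061, AT3G01570 12.82 ± 0.075 and 12.85 ± 0.045, BAN 2.84 ± 0.10 and 2.77 ± 0.22, and IKU2 4.03 ± 0.087 and 3.80 ± 0.031.

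Genes that differed between NILDOG1 and Ler were denser around DOG1 than elsewhere. Of 626 probe sets with a named gene between AT5G40000 and AT5G52000, 33 were called (5.27%), against 35 of 12741 elsewhere in the nuclear genome (0.275%), an odds ratio of 20.2 (35.3 without NILDOG1 replicate 2; 95% interval 12.1 to 33.7; two-sided Fisher's exact test, p = 3.49e-26, where genes are not independent, so the p describes these arrays). The 5 with the largest change there were AT5G43450, AT5G45540, AT5G48110, AT5G48350 and AT5G43190, which rose by 2.01. In dog1-1 against Ler the same loci held 108 calls (17.3%) against 1409 of 12741 (11.1%), an odds ratio of 1.68 (1.34 to 2.08, Fisher's exact p = 7.46e-06), which was 2.19 (1.49 to 3.14) between AT5G44000 and AT5G47500, 1.46 without dog1-1 replicate 1, and 1.20 (p = 0.0625) after centring on the hybridization controls. There AT5G43450 rose by 5.17, AT5G43150 by 2.26 and AT5G43190 by 2.23, while AT5G45630 fell by 2.15 and AT5G48350 by 2.14. All 33 probe sets called around DOG1 in NILDOG1 had the same sign in dog1-1. Simulations with dog1-1 unchanged and the Ler arrays shared gave 50.9% on average and at most 66.7%, or 86.7% with the changes of NILDOG1 set to 0.5 of their size. For NILDOG1 against dog1-1 the odds ratio was 0.947 (0.714 to 1.24, Fisher's exact p = 0.739).

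**Figure D3:**
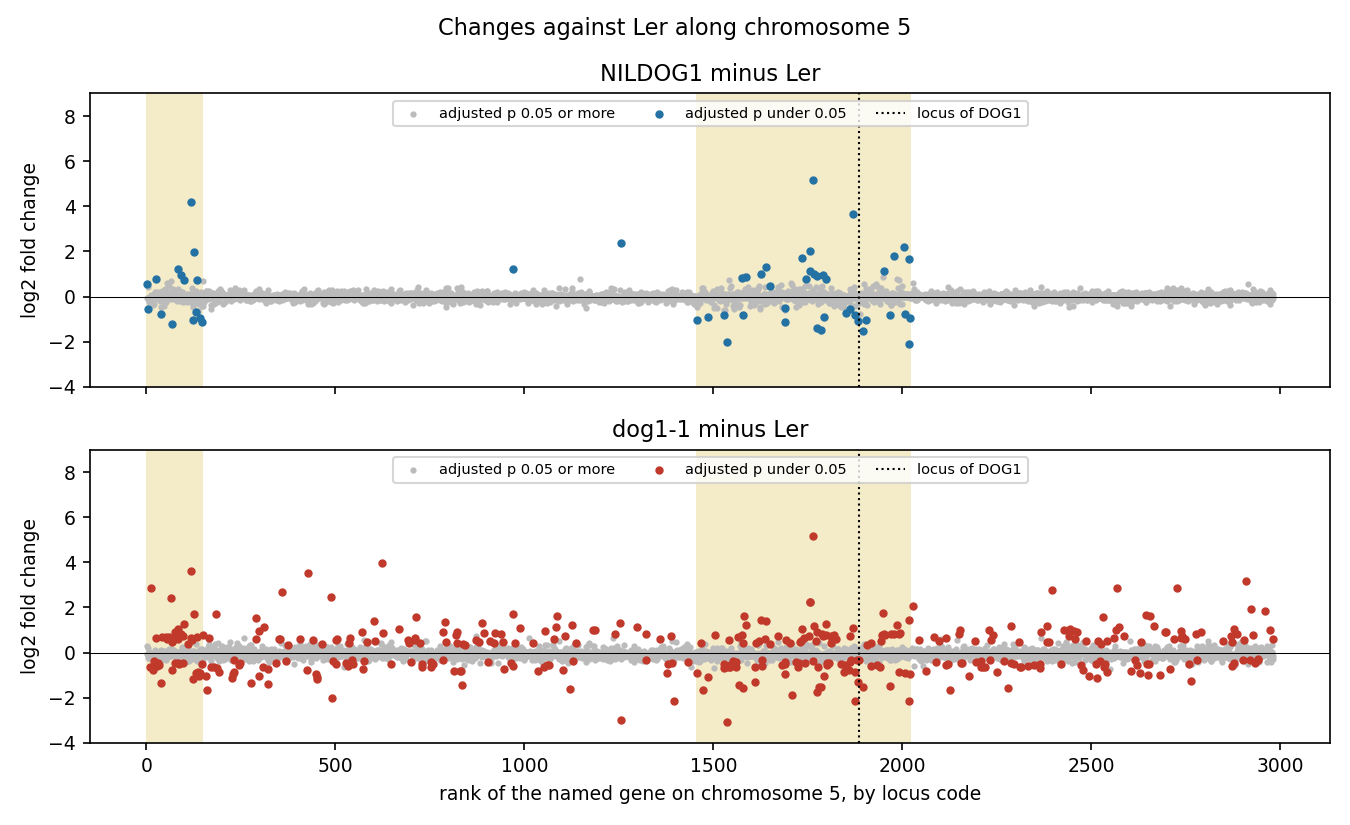
Log2 fold change against Ler of each named gene on chromosome 5 in order of locus code, for NILDOG1 (top) and dog1-1 (bottom), with coloured points for an adjusted p under 0.05, shading for 2 stretches defined after the data were seen and a dotted line at the locus of DOG1. Of the loci called in NILDOG1, 56 lay on chromosome 5 and 54 of these in the shaded stretches, whereas calls in dog1-1 lay along the whole chromosome.

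NILDOG1 against dog1-1 sets the labels' strongest DOG1 against its absence. AT5G28110 was at 7.63 ± 0.35 in NILDOG1 and at background in dog1-1 (2.27 ± 0.19, n = 3), so no fold is given. AT2G34740 was 20.8-fold higher in NILDOG1, AT1G27030 20.2-fold, HSP17.6C 13.7-fold and HSP17.6B 13.1-fold. The dehydrin genes AT4G38410 and AT1G54410 were both 21.6-fold lower, AT5G14450 was 17.1-fold lower, AT5G10120, of the EIN3-like transcription factor family, 14.5-fold (9.36 ± 0.18 in dog1-1 against 5.51 ± 0.21) and AT4G01610, a cathepsin-like protease gene, 11.9-fold (9.95 ± 0.48 against 6.37 ± 0.20). With limma 2835 probe sets passed (1124 higher and 1711 lower in NILDOG1, 781 at least 2-fold), 5377 had an unadjusted p under 0.05, and for 27.0% of all probe sets the arrays did not overlap (10% by chance).

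Heat shock genes were higher in NILDOG1 than in dog1-1: 7 rose, 0 fell and 2 did not pass, also adjusted over the list alone, with a mean of 2.1 (adjusted p = 2.31e-12, and adjusted p = 0.0463 with an estimated correlation). Of the LEA genes 10 rose, 5 fell and 20 did not pass (adjusted p = 0.191; adjusted over the list alone 11 rose and 6 fell), with AT3G22490 higher by 2.48 and AT4G39130 by 1.96. In the cell wall list 0 rose, 6 fell and 2 did not pass, also adjusted over the list alone, with a mean of -0.75 (adjusted p = 5.87e-05, but adjusted p = 0.124 with an estimated correlation); EXPA15 fell by 2.01 and CP1 by 1.07, and EXPA8 fell to background (2.51 ± 0.10), by at least 1.13. Of the photosynthesis markers 1 rose, 4 fell and 1 did not pass, also adjusted over the list alone (adjusted p = 0.0137, but adjusted p = 0.124 with an estimated correlation): RCA fell by 1.47, LHCB4.2 fell by 0.67 and LHCB4.1 was higher by 0.82. Storage protein genes split, with 2 higher (AT4G36700 by 1.17, AT2G18540 by 0.95), 2 lower (AT1G03890, -0.63; AT2G28490, a cupin-family gene, -0.33, adjusted p = 0.0401) and 1 not passed (adjusted p = 0.967), and here the mean of 0.23, the median of -0.039 and the upward test differed in sign. The oil body genes AT3G18570 and AT2G25890 were higher by 0.53 and 0.51 and the other 2 did not pass (adjusted p = 0.223); DOGL4 and BZIP53 were higher by 0.54 and 0.46 and SPT lower by 0.95 (adjusted p = 0.595). EEL was lower by 0.89, and none of the gibberellin (adjusted p = 0.105; 3 higher adjusted over the list alone), oil mobilisation (adjusted p = 0.431; 1 lower adjusted over the list alone), seed coat or endosperm genes passed, GID1A at 0.32 (adjusted p = 0.0812) and ICL at -0.38 among them. After centring on the hybridization controls, which moved every change by -0.18 (median -0.15 after it), the gains of AT3G18570, AT2G25890, DOGL4, BZIP53 and LHCB4.1 shrank and no longer passed. The difference of AT2G28490 grew in size but also no longer passed.

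The labels order the genotypes by DOG1 as dog1-1, Ler and NILDOG1, and Ler was set on that scale for the 2835 probe sets called between both ends. Its mean lay between them for 1824 (64.3%), against 47.3% to 52.2% in 100 simulations in which Ler equalled 1 of the lines. The simulations took the observed means of both lines as exact, though the probe sets were picked for the difference between these means. Picking can place Ler between them more often than simulated, so the excess alone does not show an order by DOG1. The share also depends on the normalization. After centring on the hybridization controls Ler lay between both lines for 848 of 2504 (33.9%, against 48.0% to 52.7% in simulations). With dog1-1 at 0 and NILDOG1 at 1 its median position was 0.923, and it lay closer to NILDOG1 for 2656 (93.7%). After that centring the median position was 1.09, beyond NILDOG1, and 95.7% lay closer to NILDOG1. HSP17.6C followed this pattern, with 6.36 ± 0.088 in dog1-1, 9.81 ± 0.12 in Ler and 10.14 ± 0.14 in NILDOG1, as did AT2G34740 (5.91 ± 0.33, 10.18 ± 0.22 and 10.29 ± 0.24). Probe sets called both between dog1-1 and Ler and between Ler and NILDOG1 with Ler in the middle numbered 2.

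Some genes differed from Ler in the same direction in both lines, against that order. A planned count, named genes on which both lines depart from Ler, took probe sets where the mean of both lines differed from Ler and both changes had the same sign, and asks of neither line to pass on its own. It held 812 (574 higher, 238 lower), and 2140 with 97.4% higher after centring on the hybridization controls. Outside the chromosome 5 stretches it held 270 named nuclear probe sets, against 8 called in both lines in the same direction. The whole count was 528 without Ler replicate 3 and 535 without NILDOG1 replicate 2. Called in each line on its own were 100, of which 54 were higher in both (6.08 expected from independent lists) and 44 lower in both (2.69 expected). These expected numbers take no account of the shared Ler arrays. The highest number in 100 simulations of unchanged lines sharing the Ler arrays was 1. With neither line changed hardly any probe set can pass, so that low number was fixed in advance and does not test the overlap. AT5G43450, LUL1, AT5G38780, AT5G48350, CP1 and AT4G18975 were among the probe sets called in both lines. Across probe sets, which are not independent replicates, the changes of both lines against Ler correlated at r = 0.246, below the 0.50 that shared Ler arrays alone gave in simulation, while their covariance of 0.0190 exceeded the simulated 0.00832 by 0.0107. Outside both chromosome 5 stretches there was no excess (0.00736 against 0.00798 for named nuclear genes).

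**Figure D4:**
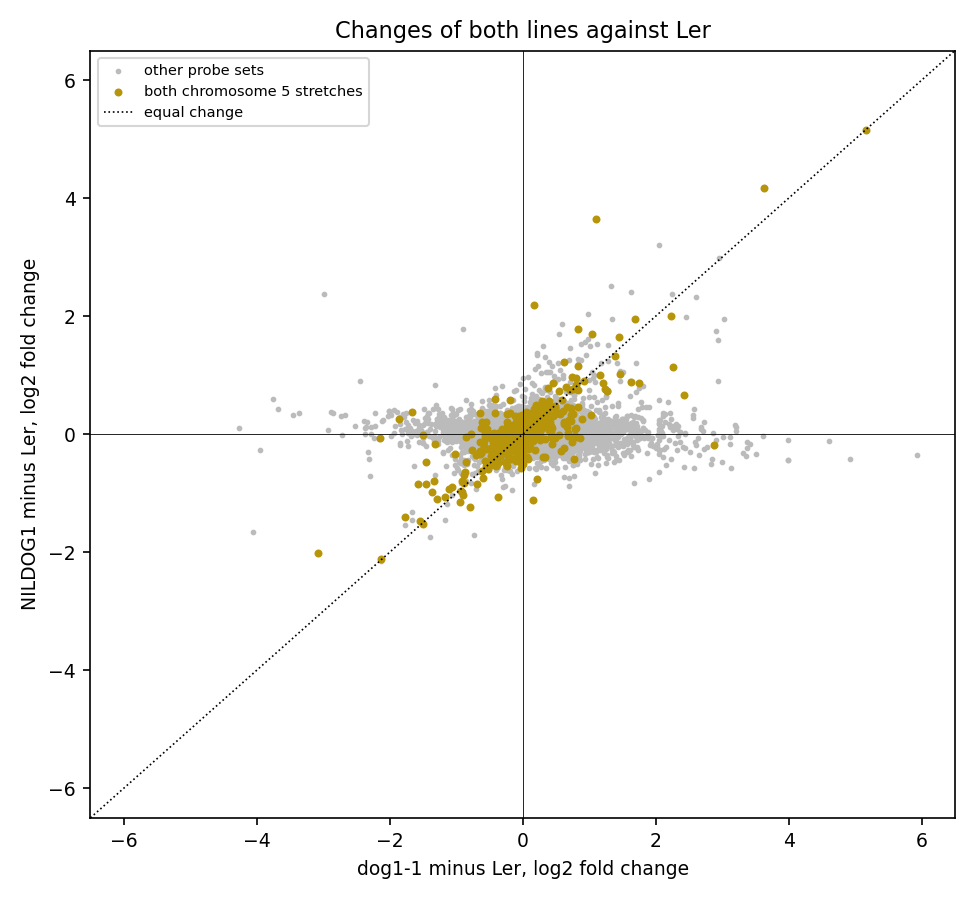
Log2 fold change of each probe set against Ler in dog1-1 (horizontal) and NILDOG1 (vertical), with those of both chromosome 5 stretches in gold and a dotted line for equal change. Gold points spread along that line (r = 0.756), and the other named genes spread mainly along the horizontal axis (r = 0.137).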

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

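The array carries control probe sets for transcripts every seed makes, which no comparison of the report used, and 12 of the 16 for actin, GAPDH and ubiquitin were higher in dog1-1 than in Ler without overlap of the arrays and past an adjusted p of 0.05. The 3 GAPDH probe sets of the first design rose by 1.5, 1.34 and 0.983 from the 3' to the 5' end, and those of the second design by 1.44 and 1.54. Those for actin rose by 0.377, 0.452, 0.455, 0.364 and 0.363, and those for ubiquitin by 0.277 and 0.404. Centring on the hybridization controls adds to these rises, since those controls were lower on the dog1-1 arrays. In NILDOG1 against Ler the 3' GAPDH probe set of the first design differed by 0.21 (adjusted p = 0.529). The 24 poly-A control probe sets, for RNA added before labelling, went the other way: their array means were 8.26 to 9.02 in dog1-1, 9.16 to 9.59 in Ler and 9.04 to 9.11 in NILDOG1, so they also separated both lines from Ler, and in dog1-1 by more than the hybridization controls (means 8.69 and 9.33).

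The array scaling tests and the comparison of the levels of these controls were chosen only after the results were seen. The scaling test, first run on all calls together, was split into rises and falls after its own result was seen, because centring moves every change up. The tests of RNA quality, from the 3' to 5' differences of the GAPDH and actin controls, and of other splits were written before. Scaling of the arrays stays open for the rises in dog1-1: centring on the hybridization controls moved the median change of all probe sets to 0.312, but those controls had been seen to be lower there, so the outcome was fixed and decides nothing, and a difference in RNA input or labelling, which the poly-A controls leave possible, was not tested. Scaling stays open for the falls as well, of which 27.1% of 1201 kept direction and passed. All 1894 rises did so, but the upward shift favours them. RNA quality also stays open: of 3 pairs of control probe sets at the 3' and 5' ends 1 separated dog1-1 from Ler, GAPDH of the first design with a mean difference of 1.53 ± 0.19 against 1.01 ± 0.15, and the same number separated the genotypes in the other comparisons. A biological explanation, that seeds without DOG1 hold more GAPDH and actin transcript, may hold as well, and these arrays cannot tell it from a difference in RNA between genotypes. Of the 10 splits of 6 arrays into 3 and 3, 1, the real one, gave as many calls in each comparison (3095, 124 and 2835, against 0 as the highest of the other splits), and 10 splits are too few for a share under 0.05.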

How the results depend on the processing

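Across 26 settings 1627 of 1725 values of named genes kept their direction and side of the threshold, 89 fell short of it, 8 came to pass it and 1 reversed; of 642 list values 622 did so, 6 fell short, 13 came to pass and 1 reversed. With arrays of the same replicate number taken as blocks in the fit, the results were 2792 (genes changed, dog1-1 against Ler), 114 (genes changed, NILDOG1 against Ler), 2567 (genes changed, NILDOG1 against dog1-1), 703 for the joint count of both lines (planned as genes on which both lines depart from Ler, though neither must pass alone) and 1637 with Ler between both lines (planned as genes ordered by DOG1 level, though only 2 passed in both steps without the block), and 2, 1 and 3 lists were called in the order of the comparisons. Other pairings of the arrays were not fitted. Without each array in turn the counts ran from 2182 to 3059, from 65 to 137 and from 2064 to 3060, the joint count from 528 to 1027, the probe sets with Ler between from 1372 to 1900, the odds ratios around DOG1 from 1.46 to 1.80, from 15.8 to 35.3 and from 0.814 to 1.02, the correlation from 0.186 to 0.304 and the lists called from 2 to 3, at 1 and at 3. NILDOG1 against Ler moved by over 1.5 times without Ler replicate 3 (80), NILDOG1 replicate 1 (65) and NILDOG1 replicate 2 (67), the joint count without Ler replicate 3 (528) and NILDOG1 replicate 2 (535), and the odds ratio around DOG1 in NILDOG1 against Ler without NILDOG1 replicate 2 (35.3). Fewer arrays give fewer residual degrees of freedom.

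A minimum log2 change of 1 left 784, 71 and 781 probe sets, 142 in the joint count (planned as genes on which both lines depart from Ler) and 528 of 781 with Ler between (planned as genes ordered by DOG1 level), by its own construction; list tests use no such minimum and were not run with it. The filter on dim probe sets left 1 list called in dog1-1 against Ler and 1 in NILDOG1 against dog1-1, array weights gave 2 in NILDOG1 against Ler, an estimated correlation 1, 0 and 1 in the order above, and fry, which asks another question, 5, 0 and 6. Without the loci around DOG1, which held 33 calls, 82 probe sets passed in NILDOG1 against Ler. Among settings added after seeing the data, removal of both stretches left 52 there and 2 lists. Without Ler replicate 1 and dog1-1 replicate 3 together 1981 (genes changed, dog1-1 against Ler) and 70 (genes changed, NILDOG1 against Ler) passed and the joint count was 470. Centring on the hybridization controls gave 5173 calls in dog1-1 against Ler, an odds ratio of 1.20 around DOG1, a joint count of 2140 (97.4% higher) and 848 with Ler between, and reversed the mean of the LEA list to 0.317 and DOGL4 (AT4G18650) in dog1-1 to 0.0058; by construction it shifts every change in dog1-1 against Ler by 0.352 (median 0.312 after it). For the other changes the cause was not tested. The correlation across genes was called unmoved where it shifted by under 0.10, its jackknife standard deviation over left-out arrays, since a simulated one ignores replicates. Calls were rare among dim genes: of the 3322 dimmest genes 10 rose and 10 fell in dog1-1, against 348 and 417 of the 3322 brightest. Of the 3321 genes next below the brightest, 403 rose and 199 fell. The cause of this pattern was not tested.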

Other observations

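All groups and tests in this part were chosen after the results were seen, except the odds ratios and the share of the same sign around DOG1. The LEA list was split into dehydrins and others because 2 dehydrins were among the largest rises, so no test of the split is given. In dog1-1 against Ler, of 6 dehydrins 4 rose (AT4G38410, AT1G54410, COR47 and LTI30) and 1 fell (AT4G39130), whereas of the 29 other LEA genes 2 rose and 10 fell. After centring on the hybridization controls 4 dehydrins were higher and 1 lower, and 3 others were higher and 7 lower. Direction also went with signal. The 6 LEA genes that rose had a median level over all arrays of 5.48 (4.11 to 12.65), and the 11 that fell 11.78 (7.94 to 12.7). Signal level and the kind of LEA protein were not told apart. Among 28 gene families, the plastid-encoded genes counted as 1, aldehyde dehydrogenase genes were higher in dog1-1 (3 rose and 0 fell of 8, adjusted p = 0.0103, but adjusted p = 0.771 with an estimated correlation), led by ALDH3F1, which rose by 1.18, and lower in NILDOG1 than in dog1-1 (0 rose and 4 fell, adjusted p = 0.0131, but adjusted p = 0.771 with an estimated correlation). Of 69 probe sets for plastid-encoded genes 1 rose and 13 fell (adjusted p = 0.0411, but adjusted p = 0.922 with an estimated correlation), and after centring on the hybridization controls 8 were higher and 5 lower. IQD genes, which encode calmodulin-binding proteins, were lower in NILDOG1 than in dog1-1 (0 rose and 3 fell of 15, adjusted p = 0.038, but adjusted p = 0.771 with an estimated correlation). Other calls, for ATG genes (adjusted p = 0.0251 in NILDOG1 against Ler and 0.0419 against dog1-1) and plastid-encoded genes in NILDOG1 against Ler (adjusted p = 0.0103), were also lost with an estimated correlation (adjusted p = 0.893, 0.905 and 0.905).

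Outside the chromosome 5 stretches 13 of 12650 named nuclear probe sets differed between NILDOG1 and Ler, 12 of them higher, and the plastid gene petN was lower (-0.69, adjusted p = 0.0449). Beside CP1 and AT5G28110 they were CYP71B6 (higher by 1.56), AT1G33590 (1.53), AT3G16530 (1.51), AT1G42705 (1.61), AR781 (1.39), AT5G20950 (1.20), YLS5 (1.15), CML42 (0.94), AT4G20480 (0.85) and AT1G18390 (0.68), and AT4G18975 was lower (-1.46). Of the 13, 12 (92.3%) had the same sign in dog1-1 and 9 were also called there; simulations with dog1-1 unchanged and Ler arrays shared gave at most 83.3% of the same sign, but up to 100% with the changes set to 0.5 of their size, so the signs alone decide nothing. The distant array of Ler replicate 1 was tested as their cause. Without it their median absolute change was 1.08 times its value and 8 of the 13 still passed. These probe sets had been picked by passing with that array included, which leaves little room for an outlying Ler array. The test could hardly come out otherwise and does not decide. NILDOG1 replicate 2 was not tested in this way. It was the highest NILDOG1 array for CYP71B6 (7.42), AT1G33590 (5.19), CP1 (7.35) and YLS5 (7.90), with NILDOG1 SDs of 0.65, 0.64, 0.48 and 0.46. AR781, AT5G28110 and AT1G18390 were highest in NILDOG1 replicate 1. A biological cause, a different effect of DOG1 on these genes or further differences between the lines, was not tested.

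Of the 69 named calls of NILDOG1 against Ler 55 fell into 2 stretches of chromosome 5, AT5G37310 to AT5G48370, which holds DOG1 (39 of 565 named loci called), and AT5G01015 to AT5G03670 (15 of 146), and the odds ratio of 20.2 around DOG1 fits a Cvi segment there, as predicted in advance. In the stretch at the start of the chromosome up to 7 of 40 neighbouring loci were called, against at most 6 in 10000 random placements. The stretch was found with this same scan, so the count is no separate test of it. Random placement also treats neighbouring genes as independent. Under that assumption the count argues against chance placement, and a second Cvi segment may lie there. Weaker binding of Cvi transcripts to the array's probes would give falls only. Of the 55 calls in both stretches 50.9% were lower in NILDOG1 (95% exact binomial interval 37.1% to 64.6%). It therefore cannot be the whole cause, though it could account for some of the falls. Weaker binding of Ler transcripts would give rises and was not tested, so differences in probe binding between both alleles are not excluded. It does not follow from these arrays which of the genes respond to DOG1.

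In dog1-1, 54 of these 55 probe sets had the same sign against Ler (98.2%) and 49 were also called, whereas simulations with dog1-1 unchanged gave at most 66.7% of the same sign, or 82.6% with the changes set to 0.5 of their size; 19 of the 55 were also called between NILDOG1 and dog1-1, among them AT5G38780 (higher by 1.07 in NILDOG1), which the same sequence alone would not give. A candidate explanation is that dog1-1 was made in NILDOG1 and carries the same Cvi sequence, so that AT5G43450, LUL1 and AT5G38780 might differ from Ler by allele rather than by loss of DOG1. The odds ratio of 1.68 around DOG1 lay between the bounds set for this in advance (2 and 1.5), and all 33 calls there had the same sign in both lines (100%, above the share set with it in advance), so that test as a whole leaves it open; the odds ratio was 2.19 in a narrower window, 1.46 without dog1-1 replicate 1 and 1.20 after centring on the hybridization controls. For the 55 probe sets as a set, the median absolute change between NILDOG1 and dog1-1 was 0.204 times that between NILDOG1 and Ler. This argues against Ler sequence in dog1-1 throughout both stretches, but a median cannot exclude it in parts of them. At AT5G48110 dog1-1 (3.55) lay near Ler (3.38) and not near NILDOG1 (5.57). The same held at TRM28 (AT5G03670), with 6.37 in dog1-1, 6.22 in Ler and 5.10 in NILDOG1. The nearest loci called in NILDOG1 against Ler, however, changed in the same direction in both lines. Beside AT5G48110 these were AT5G47550 (0.84 in dog1-1 and 1.78 in NILDOG1) and AT5G48175 (-0.91 and -0.80). Beside TRM28 it was AT5G03610 (-0.91 and -0.97). Why AT5G48110 and TRM28 differ from these neighbours was not tested. As a set, the changes of dog1-1 elsewhere are not those of shared segments, since the median gene called had 0.0375 of its change in NILDOG1, but single genes such as AT4G18975 (-1.46 in NILDOG1, -1.67 in dog1-1) and CP1 (1.95 and 3.03) stay open.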
